A study of Ovis aries with 119 samples.

How the data were processed

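RNA sequencing was done on 3 hypothalamic dissections from young Merino wethers (castrated male sheep): the arcuate nucleus (ARC), the lateral hypothalamus (LHA) and the ventromedial hypothalamus (VMH). The study held 40 animals on 5 feeding treatments, and 119 libraries entered the analysis, 39 from ARC, 40 from LHA and 40 from VMH. Group and replicate number were taken from the sample titles, and every group had 8 libraries except ARC HCP-LP-UMEI, which had 7. The series text states that 1 arcuate sample was not sequenced. Each replicate was a separate animal within a nucleus, per the labels' protocols. The labels do not tie the 3 dissections of an animal to one another, and they do not give the live weight block of an animal. Neither the animal nor the weight block could therefore be entered in the models. The matched intake contrast, whose rations were set within weight blocks, was fitted without those pairs, and p-values between nuclei treat libraries from the same animals as independent.

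The deposited table holds raw read counts per gene, whole numbers that sum to between 7.29 and 14.3 M per library, with no normalisation. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.6.0b and counted with featureCounts on the sheep build Oar_v3.1, with FastQC among the listed tools, per the submitters' processing notes. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here, so genes that share sequence with a close copy, or that overlap another gene, may have gained or lost reads in that step. The table had 27054 gene identifiers, and 2527 of them were at 0 in all 119 libraries. Every column of counts was used.

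Genes are given by their Ensembl identifiers. The files do not pair these with gene names, and 0 of the 27054 identifiers matched the reference table, which describes the assembly ARS-UI_Ramb_v3.0. The 34 gene lists fixed before the data were examined (appetite peptides, nutrient sensing, cell type and nucleus markers among them), the 16 appetite genes fixed for naming, the gene set tests and the shares of mitochondrial and blood transcripts therefore could not be run. The naming rule fixed at the same time required a gene symbol. In its place, at most 2 genes each way per comparison are named, those with the largest fold change among genes past the threshold with a mean of at least 1 count per M (CPM). This rule, and every identifier printed, was chosen after the values were seen.

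Each nucleus was fitted separately with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr on the diet groups, TMM scaling, robust dispersion estimates and a quasi-likelihood test (glmQLFit, glmQLFTest), with 1 mean per diet so that all 5 diets share an estimate of the spread. The filter left 16176 genes in ARC, 15521 in LHA and 15763 in VMH. There were 6 diet contrasts: restriction (HCP-HP-RMEI against HCP-HP-UMEI), combined deficiency (LCP-LP-UMEI against HCP-HP-UMEI), matched intake (HCP-HP-RMEI against LCP-LP-UMEI), the main effects of low protein and low phosphorus over the 4 unrestricted diets, and their interaction. A joint model of all 15 groups on 16772 genes gave the 3 contrasts between nuclei, averaged over diets, and 5 tests of whether a diet contrast differed among nuclei. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of its F statistic. Levels are CPM with TMM-scaled library sizes, as mean ± SD over libraries. Log2 CPM for principal components used a prior count of 2. Contrasts, tests and most alternatives were fixed before the data were examined.

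Count tests were tested on simulated data built from the means, library sizes and dispersions of the real libraries, with 200 genes changed in the LCP-LP-UMEI group. For combined deficiency in ARC (16176 genes), 58.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were called. In LHA (15521 genes) the shares were 55.2%, 85.1% and 98.5%, and in VMH (15763 genes) they were 52.2%, 79.1% and 95.5%. False calls were 13 of 164 in ARC, 5 of 164 in LHA and 8 of 159 in VMH. Counts were simulated for each gene independently, without the variation that genes share in the real libraries. The 200 changed genes also ease the adjustment for multiple tests. The shares may therefore be higher than in the real data, and they do not set the power behind a result of 0 calls. The median standard error of a log2 fold change for combined deficiency was 0.13 in ARC, 0.13 in LHA and 0.14 in VMH, which sets the size of change that this depth and number of animals can resolve. The biological coefficient of variation was 0.266 in ARC, 0.204 in LHA and 0.244 in VMH.

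No pair of libraries was alike enough to be a repeat of the same library: the most similar pair differed by a chi-square of 6.92 per gene in ARC, 4.18 in LHA and 4.20 in VMH. Total count, the share of counts in the 10 most abundant genes and a nucleus position score were compared between diets in 45 exact or permutation tests, and none passed the adjustment. The smallest exact p was 0.0264, adjusted p = 0.893, for a higher total count in ARC HCP-HP-RMEI (11.0 ± 1.33 M) than in ARC LCP-LP-UMEI (9.49 ± 1.04 M, n = 8 each). The position score is the mean log2 CPM of genes over 2-fold higher in a nucleus minus that of genes over 2-fold lower, along the ARC minus VMH difference for ARC and VMH and the LHA minus VMH difference for LHA, leaving out genes called between diets.

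Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, only the diets of the contrast, only the nuclei of the contrast, glmTreat against a 2-fold change, the replicate number as a block, and 2 surrogate variables from sva 3.50.0. Leaving out each library in turn and using the position score as a covariate were added after seeing the data. Diet labels were shuffled within each nucleus, 100 labelings with the real one, and group or diet labels of the joint model 21 times with the real one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.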

Results

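Gene expression was measured by RNA sequencing in the arcuate nucleus (ARC), lateral hypothalamus (LHA) and ventromedial hypothalamus (VMH) of Merino wethers of about 7 months of age, with a starting live weight of 23.7 ± 1.42 kg, after 63 days on 1 of 5 feeding treatments. These nuclei take part in the control of feed intake. The diet names give the crude protein level (HCP, 110 g per kg of dry matter; LCP, 50 g per kg) and the phosphorus level (HP, 2.5 g per kg; LP, 0.5 g per kg), each at 9 MJ of metabolisable energy per kg. Of the treatments, 4 combined these levels with free access to feed (UMEI), and HCP-HP-UMEI served as the complete diet. In the fifth, HCP-HP-RMEI, the complete pellet was rationed to what the LCP-LP-UMEI animal of the same weight block ate, as a model of hunger. Total counts, in mega (M), ran from 8.04 to 14.31 M per library in ARC (n = 39), 7.97 to 11.6 M in LHA (n = 40) and 7.29 to 13.5 M in VMH (n = 40).

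The first comparison was between nuclei. ARC stood apart from the other dissections: 14327 of 16772 genes (85.4%) differed between ARC and LHA, 7584 higher and 6743 lower in ARC, and 13654 (81.4%) differed between ARC and VMH, 6912 higher and 6742 lower. LHA and VMH were closer, with 9793 genes (58.4%), 4478 of them higher in LHA. Changes over 16-fold numbered 296 between ARC and LHA, 159 between ARC and VMH and 18 between LHA and VMH. The largest rise in ARC over LHA was ENSOARG00000015425, at 151 ± 191 CPM in ARC against 0.0761 ± 0.169 in LHA and 1.04 ± 3.16 in VMH. The largest fall was ENSOARG00000015772, at 7.47 ± 16.8 CPM in ARC, 709 ± 366 in LHA and 198 ± 213 in VMH, a log2 fold change of -6.97 (SE 0.39, adjusted p = 4.78e-33) between ARC and LHA. The quasi-likelihood test was used on the libraries of all 3 nuclei, and against a minimum change of 2-fold it called 3402, 2447 and 266 genes for the 3 pairs. Libraries of a nucleus also varied along the axis that separates the nuclei, and on PC1 the range of VMH overlapped those of ARC and LHA.

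**Figure D1:**
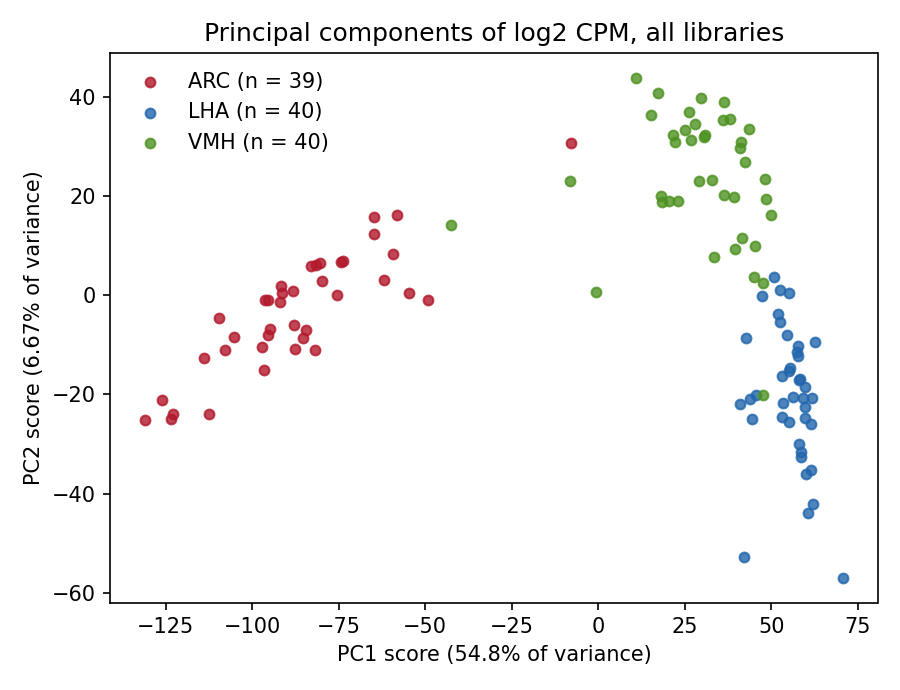
Principal components of log2 CPM over 16772 genes, with the score on PC1 (54.8% of the variance) on the horizontal axis and the score on PC2 (6.67%) on the vertical axis, 1 point per library, coloured by nucleus. ARC libraries lie between -130.8 and -7.87 on PC1, LHA libraries between 41.0 and 70.6, and VMH libraries between -42.6 and 49.9.

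Combined deficiency asks what a diet low in both protein and phosphorus changes relative to the complete diet with feed freely offered in both. In ARC, 15 genes differed, 8 higher and 7 lower on LCP-LP-UMEI, and 7 of the 15 changed over 2-fold. The largest rise was ENSOARG00000003006, from 74.4 ± 49.0 to 626 ± 387 CPM (n = 8 each), 8.43-fold with a log2 fold change of 3.08 (SE 0.48, edgeR adjusted p = 0.00291). ENSOARG00000010915 rose from 98.5 ± 37.3 to 570 ± 354 CPM, a log2 fold change of 2.53 (SE 0.43, adjusted p = 0.00377). For each of these genes 7 of 8 LCP-LP-UMEI animals lay above all 8 animals on the complete diet, where chance alone gives 0.889 of 8 for a gene not chosen on these animals. The largest falls were ENSOARG00000014562, from 7.44 ± 4.64 to 1.86 ± 0.875 CPM (log2 fold change -1.98, SE 0.43, adjusted p = 0.0467), and ENSOARG00000015333, from 2.54 ± 1.59 to 0.700 ± 0.311 CPM (log2 fold change -1.84, SE 0.36, adjusted p = 0.0184). All 8 LCP-LP-UMEI animals lay below all 8 controls for ENSOARG00000014562 (at most 3.01 against at least 3.87 CPM), and 6 of 8 for ENSOARG00000015333. Both genes were also chosen on these animals.

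The 15 calls came from the edgeR quasi-likelihood test on 16176 genes, where DESeq2 called 46, limma voom 44, edgeR with surrogate variables 77 and with a nucleus position score 79. The count was 7 (6 higher, 1 lower) without ARC HCP-HP-UMEI library 1 or without LCP-LP-UMEI library 1, 8 (6 higher, 2 lower) without LCP-LP-UMEI library 8, 30 (13 higher, 17 lower) without LCP-LP-UMEI library 7, the ARC library least like the rest, and 9 (7 higher, 2 lower) with the 2 diets alone in the fit.

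The named rises and falls differed in how far they rested on single libraries. With each of 39 ARC libraries left out in turn, ENSOARG00000003006 and ENSOARG00000010915 stayed called each time, with adjusted p up to 0.0111 and 0.0154. ENSOARG00000014562 lost its call in 23 of the 39 fits (adjusted p up to 0.150, without LCP-LP-UMEI library 1). ENSOARG00000015333 lost it in 3, without HCP-HP-UMEI library 1 (0.0743), LCP-LP-UMEI library 1 (0.0573) or LCP-LP-UMEI library 8 (0.0532). With the 2 diets alone the adjusted p was 0.0543 for ENSOARG00000014562 and 0.109 for ENSOARG00000015333.

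**Figure D2:**
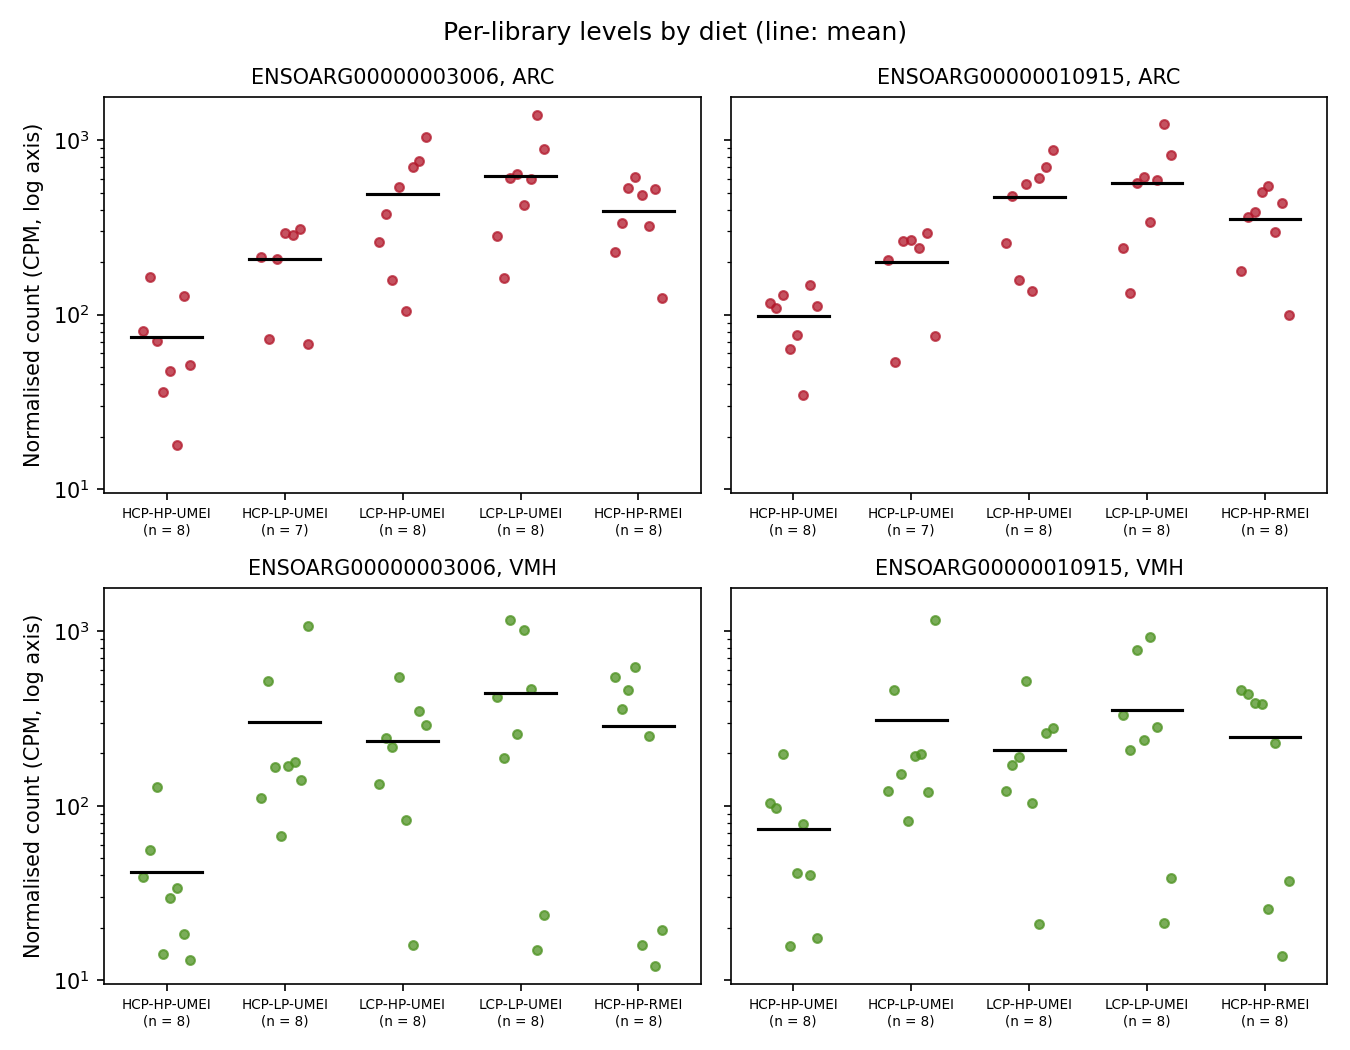
Levels of ENSOARG00000003006 and ENSOARG00000010915 per library in CPM on a log axis, for the 5 diets on the horizontal axis, in ARC (top) and VMH (bottom), with 1 point per animal and a line at the group mean. In ARC, ENSOARG00000003006 has a mean of 74.4 CPM on HCP-HP-UMEI and of 208 to 626 CPM on the other diets, and in VMH it runs from 12.1 CPM in an HCP-HP-RMEI animal to 1168 CPM in an LCP-LP-UMEI animal.

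Restriction compares animals rationed on the complete diet with animals that ate it freely. ENSOARG00000003006 averaged 395 ± 169 CPM in ARC of restricted animals against 74.4 ± 49.0, and 7 of 8 restricted animals lay above all 8 controls. Its log2 fold change was 2.41 (SE 0.47) with an adjusted p of 0.0503, just outside the threshold. ENSOARG00000010915 averaged 351 ± 154 against 98.5 ± 37.3 CPM, a log2 fold change of 1.84 (SE 0.42, adjusted p = 0.145). All 15 genes called for combined deficiency had the same sign under restriction and 12 of them had an unadjusted p under 0.05, with a median of 0.601 of the deficiency log2 fold change. These contrasts share the HCP-HP-UMEI libraries, and the 15 genes were chosen on them. No gene was called by edgeR in ARC. With each library left out in turn, 14 of 39 fits gave calls, 8 at most. At an unadjusted p under 0.05 there were 1271 genes, where independent unchanged genes give 809. Of 100 diet labelings, the real one included, 18 reached as many. DESeq2 called 23 genes, limma voom 8 and edgeR with RLE scaling 7, and surrogate variables or the position score also gave calls. ENSOARG00000003006 was among them, with an adjusted p of 0.000194 in DESeq2, 0.0109 in limma voom and 0.0442 with RLE scaling, and ENSOARG00000010915 had 0.00289 in DESeq2.

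Matched intake sets the rationed animals against the LCP-LP-UMEI animals whose intake fixed their ration, so that diet composition differs at equal intake. In ARC, ENSOARG00000003006 differed by -0.66 on the log2 scale (interval of 2 SE, -1.55 to 0.22, adjusted p = 0.870) and ENSOARG00000010915 by -0.70 (-1.51 to 0.12). Of the 15 genes called for combined deficiency, 14 lay nearer to the complete diet in the rationed animals than in LCP-LP-UMEI, and 7 had an unadjusted p under 0.05, on genes that the LCP-LP-UMEI libraries had helped to choose. Matched intake equals restriction minus combined deficiency by construction, so the 14 restate that these genes changed less under restriction. No gene was called by edgeR, 1028 had an unadjusted p under 0.05, DESeq2 called 8 and limma voom 1.

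Low protein was tested as a main effect over the 4 diets fed freely. In ARC, 14 genes differed, 10 higher and 4 lower on the low-protein diets, and 3 of the 14 changed over 2-fold. All 14 had the same sign under restriction and 11 of them had an unadjusted p under 0.05 there in edgeR. The median was 0.878 of the low protein log2 fold change, with HCP-HP-UMEI libraries shared by both contrasts. Lower intake and low protein therefore cannot be told apart for these genes. ENSOARG00000003006 rose by a log2 fold change of 2.16 (SE 0.34, adjusted p = 0.00203), with 493 ± 327 CPM on LCP-HP-UMEI and 208 ± 102 on HCP-LP-UMEI (n = 7). ENSOARG00000010915 rose by 1.89 (SE 0.30, adjusted p = 0.00203), with 473 ± 268 and 200.4 ± 96.9 CPM on the same diets. The largest falls were small: ENSOARG00000013964 had a log2 fold change of -0.44 (SE 0.09, adjusted p = 0.0308), and ENSOARG00000011427 of -0.37 (SE 0.08, adjusted p = 0.0402). The lists for low protein and combined deficiency share 6 genes, all with the same sign, and both contrasts use the HCP-HP-UMEI and LCP-LP-UMEI libraries. The low protein change is also a part of the combined deficiency change by construction, so this overlap is not independent evidence. The 14 calls compare with 41 in DESeq2, 30 in limma voom, 58 with surrogate variables and 47 with the position score, and with 9 (7 higher, 2 lower) without ARC HCP-HP-UMEI library 5. Over 39 fits with a library left out, ENSOARG00000013964 lost its call in 4 (adjusted p up to 0.0829) and ENSOARG00000011427 in 15 (up to 0.0762), and with only the 4 diets in the fit they had 0.0902 and 0.0935.

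Low phosphorus changed no gene past the threshold in ARC. ENSOARG00000003006 had a log2 fold change of 0.91 (SE 0.32, adjusted p = 0.473) and ENSOARG00000010915 of 0.65 (SE 0.29, adjusted p = 0.552). These values average over both protein levels. On HCP-LP-UMEI, where phosphorus alone was low, the genes averaged 208 ± 102 and 200 ± 96.9 CPM, against 74.4 ± 49.0 and 98.5 ± 37.3 on HCP-HP-UMEI. For each gene 5 of 7 HCP-LP-UMEI animals lay above all controls, where chance alone gives 0.778 for a gene not chosen on these controls. Both genes were so chosen, and this pair of diets was not tested. All 15 genes called for combined deficiency had the same sign under low phosphorus and 14 of them had an unadjusted p under 0.05, again on shared libraries. The combined deficiency change is by construction the sum of the low protein and low phosphorus changes. Genes chosen for a large sum tend to share its sign in both parts, so these counts are no separate evidence of a phosphorus effect. The edgeR test called 0 genes with 1393 at an unadjusted p under 0.05 (896 higher and 497 lower), and DESeq2 and limma voom called 0. The interaction of protein and phosphorus also gave 0 calls in edgeR, DESeq2 and limma voom, with 946 genes at an unadjusted p under 0.05 and a log2 interaction of -1.14 (SE 0.64, adjusted p = 0.750) for ENSOARG00000003006.

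LHA showed no called gene in any of the 6 diet contrasts. The largest riser in ARC was near the floor here and the next was low but measurable: ENSOARG00000003006 averaged 0.913 ± 1.01 CPM on HCP-HP-UMEI and 1.26 ± 1.02 on LCP-LP-UMEI, and ENSOARG00000010915 averaged 9.47 ± 4.67 and 9.20 ± 4.62 CPM. The largest falls of ARC for combined deficiency had the same sign here without a call. The log2 fold change was -1.52 (SE 0.54) for ENSOARG00000014562 and -1.06 (SE 0.42) for ENSOARG00000015333, both at low counts. Of the 15 genes called in ARC for combined deficiency, 14 had the same sign in LHA and 3 passed when adjusted over those 15 alone. These are dissections from the same 40 animals and are not independent evidence. The genes at an unadjusted p under 0.05 in edgeR were 400 for restriction, 472 for combined deficiency, 664 for matched intake, 348 for low protein, 378 for low phosphorus and 771 for the interaction, against 776 for independent unchanged genes. For each contrast, 40 to 77 of 100 diet labelings, the real one included, reached as many. DESeq2 called 3 genes for combined deficiency and 1 for matched intake, limma voom 2 and 1, and both called 0 for the other contrasts.

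VMH had no called gene either. ENSOARG00000003006 averaged 41.6 ± 37.9 CPM on HCP-HP-UMEI, 304 ± 343 on HCP-LP-UMEI, 235 ± 166 on LCP-HP-UMEI, 445 ± 435 on LCP-LP-UMEI and 287 ± 251 on HCP-HP-RMEI (n = 8 each). Its log2 fold change for combined deficiency was 3.42 (SE 0.84, edgeR adjusted p = 0.250), larger in size than in ARC but with a wider error, and 6 of 8 animals lay above all controls. For low phosphorus it was 1.90 (SE 0.56, edgeR adjusted p = 0.447) and for low protein 1.52 (SE 0.55, edgeR adjusted p = 0.825). ENSOARG00000014562, the largest fall in ARC, had a log2 fold change of -1.88 here (SE 0.39, edgeR adjusted p = 0.250). For that gene 8 of 8 LCP-LP-UMEI animals lay below all controls (at most 1.30 against at least 2.03 CPM). Of the 15 genes called in ARC, 12 had the same sign in VMH and 8 passed when adjusted over those 15 alone, in the same animals. For each contrast, 19 to 72 of 100 diet labelings, the real one included, reached the number of genes at an unadjusted p under 0.05. These numbers were 572 for restriction, 1376 for combined deficiency, 1540 for matched intake, 830 for low protein, 1228 for low phosphorus and 568 for the interaction, where independent unchanged genes give 788. DESeq2 called 1, 6, 1, 4, 1 and 0 genes in that order, and limma voom called 1 gene for low phosphorus and 0 for the rest.

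**Figure D3:**
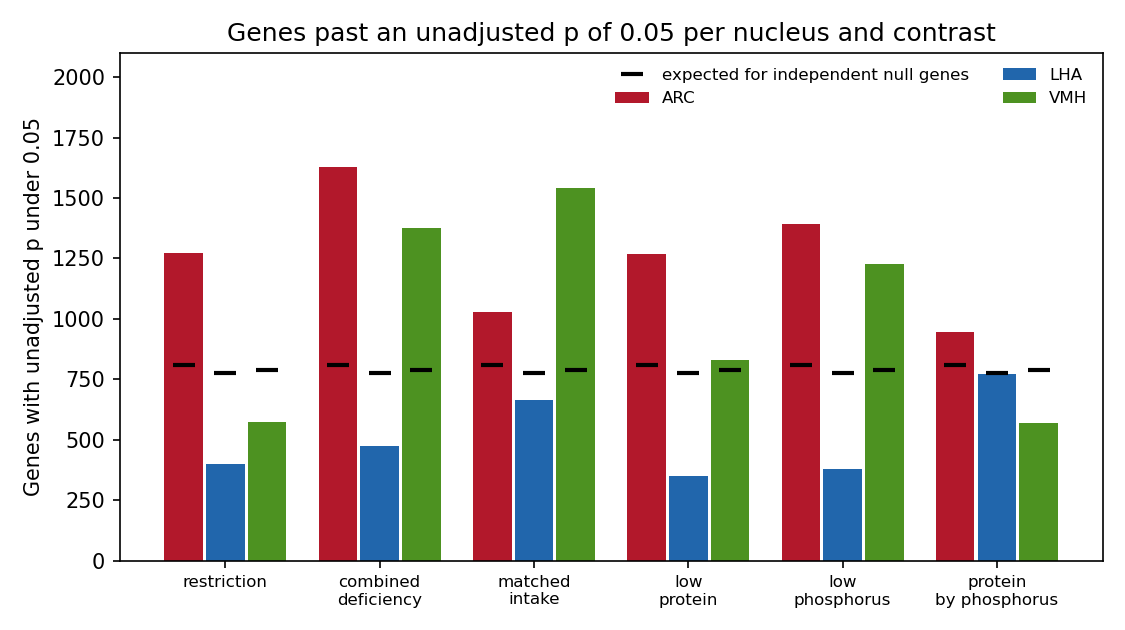
Number of genes with an unadjusted p under 0.05 (vertical axis, from 0) for the 6 diet contrasts, with a bar per nucleus and a black dash at the number that independent unchanged genes would give. ARC reaches 1630 genes for combined deficiency, where the dash is at 809 and 10 of 100 shuffles of the diet labels (the real one included) reach as many, and LHA stays at or under 771.

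Whether a diet contrast differed among nuclei was tested directly on 16772 genes. No gene was called for restriction, combined deficiency, matched intake or low protein in edgeR. At an unadjusted p under 0.05 there were 591, 776, 636 and 550 genes, against 839 for independent unchanged genes. No other tool was run on these tests. Without VMH HCP-LP-UMEI library 1 the restriction test called 5 genes. The response of ENSOARG00000010915 to combined deficiency was higher by 2.58 on the log2 scale in ARC than in LHA and by 0.26 than in VMH, with an adjusted p of 0.467 over all genes. Adjusted over the genes called in ARC alone, a test added after the values were seen, ENSOARG00000010915 was the 1 gene of 15 to pass for combined deficiency (0.0315), and 4 of 14 passed for low protein, ENSOARG00000010915 (0.0209) and ENSOARG00000011427 (0.00322) among them. These genes were chosen for their change in ARC, which favours a larger change there, so these values do not establish a difference among nuclei. Low phosphorus gave 1 gene, ENSOARG00000013029 (adjusted p = 0.000345), whose value rested on a few libraries: 589 CPM in VMH HCP-LP-UMEI library 1, 83.9 in ARC HCP-HP-UMEI library 3 and 25.4 in ARC LCP-HP-UMEI library 5, with no other library above 6.83.

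The last comparison set the responses to restriction and to combined deficiency side by side. Across 16176 genes in ARC their log2 changes correlated at 0.643, where unchanged groups against the same controls gave 0.494 on average, and genes are not independent replicates. The covariance was 0.0377 against a simulated 0.0313 ± 0.0209 (SD of 1000 draws), a difference of 0.00640, and 28.5% of draws were at least as large. With the controls divided so that each contrast had 4 of its own, the covariance was 0.00865 and 0.0138 for the 2 assignments, against a simulated 0.00129 ± 0.0264. The covariance was 0.0143 in LHA and 0.0194 in VMH, below the simulated 0.0174 and 0.0265. A shared response over all genes was not distinguishable from the shared controls in any of the 3 nuclei.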

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

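All tests of explanations in this part were chosen after the result was seen. A library was picked out where its gap to the nearest other library of its group was large for the group's range. This happened in 15 of 85 sets of values, and chance alone gives about 1 in 20 for independent, normally distributed values. Some sets share libraries and the distribution was not tested. The excess over that rate is therefore not by itself evidence of unusual libraries. Total count was high in ARC HCP-HP-UMEI library 4 (14.31 M, next 11.0, gap over range 0.580) and VMH HCP-LP-UMEI library 8 (13.5 M, next 10.4, gap 0.602). The share of counts in the 10 most abundant genes stood apart in ARC HCP-HP-RMEI library 3 (7.23%, gap 0.737), ARC HCP-HP-UMEI library 1 (10.1%, gap 0.722), LHA HCP-HP-RMEI library 3 (11.5%, gap 0.574) and LHA HCP-HP-UMEI library 4 (6.47%, gap 0.542). By median Spearman correlation with the rest of their nucleus, VMH LCP-LP-UMEI library 6 (0.895) and LHA LCP-HP-UMEI library 3 (0.935) were the least similar, and no diet contrast of their nucleus gained a call in edgeR without them. In ARC the least similar was LCP-LP-UMEI library 7 (0.943), which also had the lowest nucleus position score of ARC (-1.22). Without it, ARC restriction had 8 calls in place of 0 and combined deficiency 30 in place of 15.

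Levels of named genes also stood apart in single animals. ENSOARG00000003006 was high in VMH HCP-HP-UMEI library 3 (128 CPM, gap 0.632) and VMH HCP-LP-UMEI library 8 (1079 CPM, gap 0.550), and ENSOARG00000010915 in the latter (1161 CPM, gap 0.646). ENSOARG00000014562 was high in ARC HCP-HP-UMEI library 1 (18.6 CPM, gap 0.740) and ARC HCP-LP-UMEI library 1 (8.31 CPM, gap 0.803). Its fall on LCP-LP-UMEI is measured against the group that holds the former. The lowest animal of that group, at 3.87 CPM, still lay above all 8 LCP-LP-UMEI animals (at most 3.01 CPM).

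The nucleus position score stood apart in ARC HCP-LP-UMEI library 7 (gap 0.756), LHA HCP-LP-UMEI library 2 (gap 0.539), VMH HCP-HP-RMEI library 6 (gap 0.736) and VMH HCP-HP-UMEI library 1 (gap 0.621). Among ARC libraries the first principal component held 24.6% of the variance. Its gene loadings correlated with the ARC minus VMH fold change at 0.796 in size across 16163 genes, so where the tissue was dissected is a candidate source that may account for it. Diet as the source is argued against, since 4.29% of the component's variance lay between diets, and so is library size, since 1.62% went with total count. The first component followed position less in LHA (0.288) and VMH (0.342), and the second component followed it more there (0.491 and 0.534). The first component was also set against the running number of the library within its nucleus in the count table. Spearman's rho was -0.450 in LHA (permutation p = 0.00376), 0.387 in VMH (p = 0.0138) and 0.232 in ARC (p = 0.156). For Pearson's r the adjusted permutation p was 0.0527 in LHA and in VMH. In ARC the running number was not balanced over diets. The HCP-LP-UMEI libraries had numbers from 3 to 15, whereas those of the other diets ran up to between 34 and 40. An effect of library order, if there was one, would enter the ARC low protein, low phosphorus and interaction contrasts, and it was not modelled. Differences between animals in the make-up of the nucleus itself were not tested and stay open.

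The low phosphorus response of ENSOARG00000013029 differed among nuclei, with an adjusted p of 0.000345. Without VMH HCP-LP-UMEI library 1 (589 CPM) the adjusted p was 0.00338, and the next highest values were 83.9 and 25.4 CPM in single ARC libraries. In shuffles of diet within nucleus, 10 of 21 labelings called at least 1 gene and the highest of the others called 19. These shuffles could give an animal different diets in different nuclei, whereas each animal had 1 diet. Effects shared by the dissections of an animal can then pass for differences among nuclei. The shuffles therefore cannot decide, and chance is not excluded.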

How the results depend on the processing

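Leaving out single libraries and using the position score as a covariate were chosen after seeing the data. No result changed direction. The gene list tests were not run, for want of gene names, nor were camera and fry on them. The cause of the changes below was not tested, apart from fewer samples where diets or libraries were left out. For ARC restriction (0 calls), RLE scaling gave 7, DESeq2 23, limma voom 8, surrogate variables 14 and the position score 12. For ARC combined deficiency (15), DESeq2 gave 46, limma voom 44, surrogate variables 77, the position score 79 and only the 2 diets 9. For ARC matched intake (0), DESeq2 gave 8, limma voom 1 and the position score 2, and for ARC low protein (14), DESeq2 gave 41, limma voom 30, surrogate variables 58 and the position score 47. ARC low phosphorus and the interaction gave 0 under every setting run. In LHA (0 throughout), DESeq2 gave 3 for combined deficiency and 1 for matched intake, and limma voom 2 and 1. In VMH (0 throughout), DESeq2 gave 1 for restriction, 6 for combined deficiency, 1 for matched intake, 4 for low protein and 1 for low phosphorus. There, limma voom gave 1 for low phosphorus, only the 2 diets 1 for combined deficiency, surrogate variables 1 each for restriction, combined deficiency and low protein, and the position score 2 for restriction. Against a 2-fold change the nuclei differed in 3402, 2447 and 266 genes, by construction fewer.

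Leaving out each library in turn gave 0 to 8 calls for ARC restriction, 7 to 30 for combined deficiency, 0 to 3 for matched intake and 9 to 18 for low protein. For restriction, calls appeared without HCP-LP-UMEI library 2 (5), 4 (7), 5 (6) or 7 (6), HCP-HP-UMEI 2 (1), LCP-LP-UMEI 1 (5), 2 (4) or 7 (8), LCP-HP-UMEI 3 (1) or 5 (3), and HCP-HP-RMEI 4 (1), 5 (4), 6 (7) or 8 (3). For matched intake they appeared without LCP-LP-UMEI 1 (1) or 2 (3), or HCP-HP-RMEI 5 (1). In VMH the ranges were 0 to 1 for restriction (HCP-HP-RMEI 4 or 5), 0 to 2 for matched intake (LCP-LP-UMEI 7) and 0 to 3 for low phosphorus (HCP-HP-UMEI 3), and in LHA all were 0. The test of a restriction response that differs among nuclei (0) gave 5 without VMH HCP-LP-UMEI library 1. Among named genes, the adjusted p of ENSOARG00000014562 for combined deficiency was 0.0618 without the filter and 0.0244 to 0.150 with a library left out (0.0568 without LCP-LP-UMEI library 7). For restriction, ENSOARG00000003006 gained a call with RLE scaling (0.0442), DESeq2 (0.000194), limma voom (0.0109), surrogate variables (6.24e-05), the position score (0.000158) and without LCP-LP-UMEI library 7 (0.0357), and ENSOARG00000010915 with DESeq2 (0.00289), surrogate variables (0.00133) and the position score (0.00412).

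The labels do not say that replicate numbers pair libraries, and many same-numbered pairs did not deviate together: they correlated at a mean of 0.0352 in ARC, 0.0304 in LHA and 0.0249 in VMH, with single pairs from -0.477 to 0.538, and 11 of 39, 5 of 40 and 5 of 40 libraries correlated best with their own number. Numbers shuffled within diets gave 4.90, 5.04 and 4.93 on average, and 1.70%, 54.7% and 55.1% of 1000 shuffles gave at least as many, so a weak tie in ARC is not ruled out. Within each group the replicate numbers rise with the running number of the library. A shared number may therefore reflect a similar place in that order and not a weight block. With the number as a replicate block, ARC combined deficiency had 8 calls, and the adjusted p was 0.119 for ENSOARG00000014562, 0.0698 for ENSOARG00000015333 and 0.0567 for ENSOARG00000013964 under low protein. The block moved no other count by over 1.5 times.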

Other observations

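All tests in this part were chosen after the result was seen. Some genes were on in some animals and off in others. A gene was counted where log2 CPM had a gap over 2 with at least 3 libraries on each side, a mean log2 CPM over 1 above the gap and a mean count over 1. This held for 27 genes in ARC, 21 in LHA and 22 in VMH, and 17 genes had it in all 3 nuclei. ENSOARG00000002980, for example, was on in 7 libraries on HCP-HP-UMEI, 4 on HCP-LP-UMEI, 5 on LCP-HP-UMEI, 4 on LCP-LP-UMEI and 8 on HCP-HP-RMEI in each of the nuclei. The rule found 96.0% of 50 planted genes. None of the 17 was called in a diet contrast by edgeR, and 6 of them had a change over 2-fold in at least 1 contrast.

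The numbers of libraries in which these genes were on, diet by diet, were equal between nuclei in 199 of 221 comparisons, where 10000 shuffles of diet within nucleus gave 64.8 on average and 92 at most (permutation p = 1e-04, the smallest they can give). A property of the animal, such as a variant of the gene or a copy that the reference lacks, is a candidate explanation. Diet as the whole cause is argued against, since all 17 genes had both on and off libraries within at least 1 diet in LHA. Fisher's exact test on LHA counts by diet had a smallest p of 0.0161 and a smallest adjusted p of 0.241 over the 17 genes. Whether reads fail to align or the gene is silent stays open.

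The 15 genes called in ARC for combined deficiency were weighed against technical explanations. With the position score as a covariate all 15 were still called, at a median of 1.00 times their log2 fold change. The total rose to 79. The score itself averaged 1.03 ± 1.10 on LCP-LP-UMEI and 1.03 ± 0.761 on HCP-HP-UMEI (exact permutation p = 0.988). A shift along the ARC minus VMH axis is therefore argued against as the whole cause. The score does not follow the ARC minus LHA difference, which was 8.05 for ENSOARG00000003006 and 4.93 for ENSOARG00000010915 on the log2 scale. Dissection toward LHA was not tested and stays open. A part played by a few extreme libraries stays open. For 15 of 15 genes at least 7 of 8 LCP-LP-UMEI libraries lay beyond the control median, but the genes were called on these libraries, and the count fell to 7 without HCP-HP-UMEI library 1 or without LCP-LP-UMEI library 1. Lower intake, and not diet composition, may underlie the calls. Of the 15 genes, 6 differed between HCP-HP-RMEI and LCP-LP-UMEI when adjusted over the 15 alone, but the LCP-LP-UMEI libraries had chosen the genes, so the explanations cannot be told apart here.

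Diet labels were shuffled within each nucleus, 100 labelings with the real one. The number of calls was used only where the real labels gave calls, so the measure depended on the outcome. For ARC combined deficiency 1 of 100 labelings, the real one, gave 15 calls and the highest other gave 5. For ARC low protein 2 of 100 gave at least 14 calls and the highest other gave 136. By the number of genes at an unadjusted p under 0.05, 10 of 100 reached the 1630 of combined deficiency (highest other 3281) and 18 the 1268 of low protein (2981). Few labelings reached the calls, but with a measure picked this way chance is not excluded for either contrast. These shares are not adjusted for the number of contrasts. Single labelings of contrasts without a real call gave up to 167 calls in ARC (matched intake), 2162 in LHA (restriction) and 397 in VMH (low protein). The reason for these high counts was not tested.

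For contrasts with no call the number of genes at an unadjusted p under 0.05 was used, and chance could not be excluded for any. In ARC, 18 of 100 labelings reached the 1271 genes of restriction (highest other 3445), 28 the 1028 of matched intake (3351), 17 the 1393 of low phosphorus (3946) and 39 the 946 of the interaction (3477). In LHA, 72 reached the 400 of restriction (5295), 53 the 472 of combined deficiency (3327), 42 the 664 of matched intake (4846), 77 the 348 of low protein (1777), 75 the 378 of low phosphorus (2514) and 40 the 771 of the interaction (3325). In VMH, 54 reached the 572 of restriction (2515), 22 the 1376 of combined deficiency (2621), 19 the 1540 of matched intake (2797), 47 the 830 of low protein (3297), 22 the 1228 of low phosphorus (2715) and 72 the 568 of the interaction (2280).

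Group labels of the joint model were shuffled to 21 labelings with the real one. For each pair of nuclei 1 of 21 labelings, the real one, reached the count: 14327 genes against 134 in the highest other for ARC and LHA, 13654 against 19 for ARC and VMH, and 9793 against 1 for LHA and VMH, so chance is excluded. For responses that differ among nuclei, diets were shuffled within nucleus and genes at an unadjusted p under 0.05 were counted. For restriction, 17 of 21 reached the 591 genes (highest other 3091). The 776 of combined deficiency were reached by 14 (1984), the 636 of matched intake by 14 (2320) and the 550 of low protein by 16 (1537). These shuffles broke the tie of 1 diet per animal over the nuclei, so they cannot decide, and chance is not excluded.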
